A study of Mus musculus with 10 samples.

How the data were processed

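Sorted macrophages and dendritic cells from the mouse colon were measured on 10 Affymetrix Mouse Gene 1.0 ST arrays, 1 sorted sample per array. The deposited values were log2 values, 35557 features per array, and the authors' processing notes name GCOS 1.4 without saying which steps it performed. How the log2 values were normalized is not given in the sources used here. The log2 scale was checked on the values, which reached 13.59, and array medians lay between 6.181 and 6.288. Detection calls and background estimates were not used here, so signal over background is unknown, and low levels compress differences. No genome build is named, so no positions are given.

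Arrays were grouped by the gates in their titles, CD11chi F4/80-negative dendritic (3 arrays), CD11cint F4/80int (2), CD11cint F4/80hi macrophage (3) and CD11c-negative F4/80hi macrophage (2). Of the probe sets, 21789 had 1 gene symbol and were used. Another 1621 had several symbols and 12147 had none in the platform annotation, and these were left out. Current symbols were assigned through Entrez identifiers for 21698 probe sets, and 91 kept the symbol in the annotation. The probe set with the highest mean log2 stood for each of 999 genes with several probe sets. The other probe sets of named genes were compared in 37 cases, and in 0 of them did another probe set differ by more than 1 in the opposite direction. For Top2a, called in 4 comparisons, the other probe set gave -0.22, -0.05, -0.07 and -0.24 against -2.46, -2.33, 1.87 and 1.75, with opposite signs in the last 2, so its calls rest on 1 probe set. A gene was tested if its value lay above the array's own median on at least 2 arrays, which left 12030 genes, 60.3% of 19938 symbols.

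A linear model with a mean for each gate was fitted to all 10 arrays with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), with 6 residual degrees of freedom. All 6 differences between gates were tested, 2-sided, with Benjamini-Hochberg adjustment within each comparison and a threshold of 0.05. Standard errors of differences are moderated ones from this model, and spreads of a gate are SDs over its arrays. Because each gate enters several comparisons, these are not independent of each other. For the comparisons that share the CD11chi dendritic arrays, 100 sets of unchanged gates were simulated, which gave the correlation and covariance that sharing adds with no real difference. Unchanged gates called no genes in common, so the simulated overlap of calls did not measure what sharing adds to the observed overlap.

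The 40 gene lists hold 625 distinct symbols and were written before the data were examined, as were the comparisons, the threshold and the naming rule. Lists with at least 5 tested members were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over 198 tests, and again with a correlation estimated for each list. Counts adjusted over the list alone used the same p-values adjusted within the list. Camera compares a list with all other tested genes. Genes were named by rule. The rule took the 10 highest and 10 lowest genes past the threshold whose arrays did not overlap (5 and 5 between the macrophage gates and for F4/80int cells against CD11c-negative macrophages), and the sort marker genes. It also took up to 4 members of each list past the threshold with the largest differences or, if none passed, up to 2 with the highest levels.

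The position of an array was computed, for each gene that differed by more than 1 between CD11cint macrophages and CD11chi dendritic cells, as its distance from the dendritic mean divided by the distance between both means. The median over genes was taken. The pipeline was tested on simulated data with 50 changed genes of each size, in 3 of the comparisons, CD11cint macrophages against CD11chi dendritic cells, F4/80int against CD11chi dendritic cells and F4/80int cells against CD11c-negative macrophages. At a change of 1 it recovered 80%, 62% and 64% of changed genes, at 2 it recovered 92%, 96% and 88%, in that order, and 2.1%, 3.5% and 5.9% of calls were false.

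The alternatives were quantile normalization, scaling to the same 75th percentile, no filter, a filter on the mean over all arrays, the mean of a gene's probe sets, every probe set tested on its own, no intensity trend, only the gates compared in the model, a replicate block, no empirical Bayes prior, CD11c-negative macrophages as the reference of the position, and leaving out each array in turn. After the values were seen, the fits without 3 arrays that share a pattern within their gates and without 2 arrays with lymphocyte transcripts were added. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.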

Results

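RNA from macrophages and dendritic cells of the mouse colon was measured on 10 Affymetrix Mouse Gene 1.0 ST arrays, each with 1 sorted cell sample. The cells came from Rag2-deficient mice, which have no T or B cells of their own, after transfer of both CD45RBhigh and CD45RBlow CD4 T cells from wild-type spleens. The labels describe these recipients as free of colitis and as normal controls. Low-density cells of the digested colon wall were sorted as live cells with high MHC class II and without the lymphocyte markers CD19, CD3, TCRβ and TCRγδ. Gates on CD11c and F4/80, surface proteins carried by many dendritic cells and macrophages, gave 4 groups. CD11chi dendritic cells without F4/80 had 3 arrays, and CD11cint F4/80hi cells, called CD11cint macrophages here, had 3. CD11c-negative F4/80hi cells, called CD11c-negative macrophages, had 2. Cells with intermediate CD11c and intermediate F4/80, which the sample titles call dendritic, had 2 and are called F4/80int cells. The series title concerns the fate of Ly6Chi monocytes in the inflamed colon, and arrays of inflamed colons were not analysed here. The comparisons between gates ask how these resident populations differ.

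Values reached 13.59 on the log2 scale, with array medians between 6.181 and 6.288, and 12030 genes were tested in each comparison. The number of arrays per gate, 2 or 3, limits the precision of each value. The labels do not say whether replicates came from separate mice or sorts. Adjusted p-values weigh a difference against the spread between samples within gates, which was pooled over all gates and may be technical. Each difference below is the first gate minus the second on the log2 scale, given with its standard error (SE). Genes in the lowest part of the range have compressed differences. The gene lists, the comparisons and the rule for naming genes were set before the data were examined. Of 198 list tests 113 passed with a preset correlation between genes and 0 with an estimated correlation, where the adjusted p ran from 0.0837 to 0.996.

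The gates were set on the proteins CD11c and F4/80, so differences in Itgax and Adgre1 between gates are no finding. CD11b and CD103, the proteins of Itgam and Itgae, are not named in these gates. Adgre1, which encodes F4/80, had means of 6.76 ± 1.03 (SD, n = 3) in CD11chi dendritic cells, 8.82 ± 1.71 (n = 2) in F4/80int cells, 10.73 ± 0.13 (n = 3) in CD11cint macrophages and 11.22 ± 0.11 (n = 2) in CD11c-negative macrophages. Itgax, which encodes CD11c, had means of 10.17, 10.36, 10.21 and 8.18 in the same order, and so was lower in the CD11c-negative gate without following the split into CD11chi and CD11cint. Itgam, the gene of CD11b, had means of 7.81, 8.86, 9.33 and 9.69. H2-Ab1, an MHC class II chain, lay between 12.35 and 12.46 in every gate. Itgae, the gene of CD103, for which the cells were also stained, had means of 10.21, 9.92, 6.44 and 6.08. Over all tested genes the first principal component held 49.3% of the variance and set both macrophage gates, from -29.3 to -20.5, apart from the CD11chi dendritic arrays, from 28.8 to 37.1. F4/80int replicate 1 lay at 26.7 on it and F4/80int replicate 2 at 0.3.

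**Figure D1:**
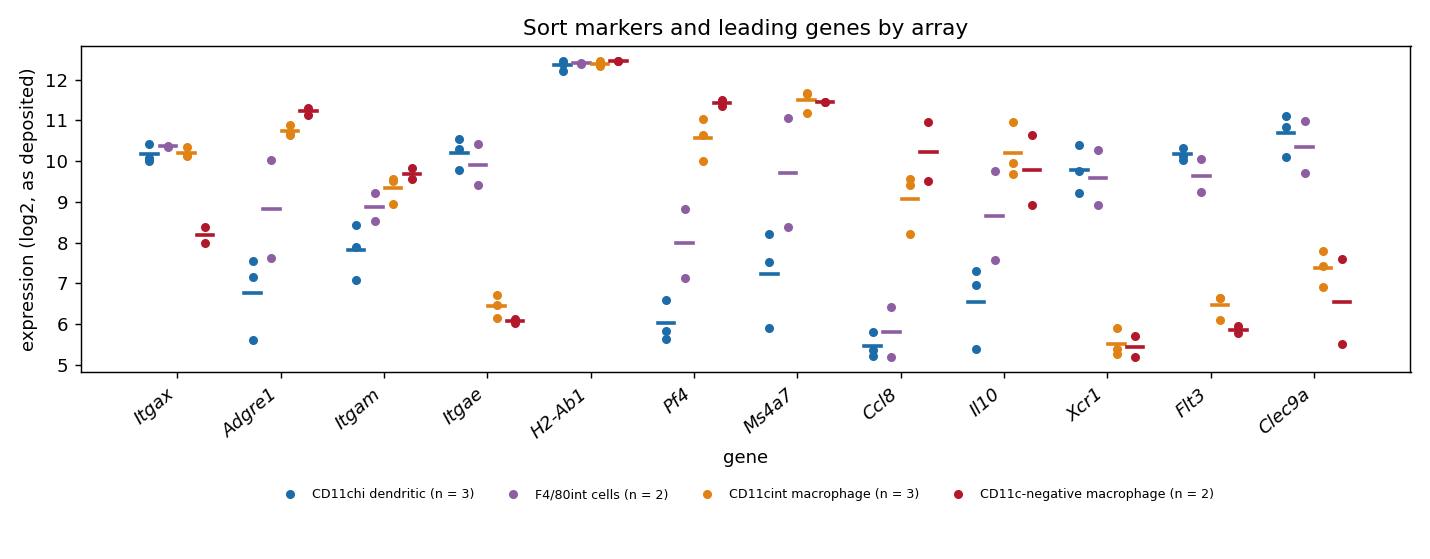
Expression on the log2 scale as deposited (vertical axis) of the sort marker genes and 7 genes with large differences (horizontal axis), 1 point per array and 1 bar per gate mean, with n = 3, 2, 3 and 2 arrays from left to right within each gene. Pf4 had means of 6.02 in CD11chi dendritic cells and 10.56 in CD11cint macrophages, and the F4/80int arrays lie far apart for Adgre1 and Ms4a7.

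CD11cint macrophages (n = 3) differed from CD11chi dendritic cells (n = 3) in chemokine, complement receptor and cytokine genes, among others. Pf4, a chemokine also stored in platelets, was higher in the macrophages by 4.54 ± 0.42 (SE), with means of 10.56 and 6.02. Ccl12 was higher by 3.97 ± 0.57 and Ccl8 by 3.60 ± 0.45, and both encode chemokines that attract monocytes. Il10, an anti-inflammatory cytokine, was higher by 3.65 ± 0.67, C3ar1, the receptor of complement fragment C3a, by 3.87 ± 0.73, and Fcgr4, an activating IgG receptor, by 3.53 ± 0.49. Ms4a7 was higher by 4.27 ± 0.65, Mmp13, a collagenase, by 3.83 ± 0.80, and Spic, a transcription factor of iron-recycling macrophages, by 3.82 ± 0.50. In the opposite direction lay Xcr1, the chemokine receptor of type 1 dendritic cells, at -4.27 ± 0.37, Clec9a, a receptor for dead cells on the same subset, at -3.31 ± 0.52, and Flt3, the cytokine receptor needed for dendritic cell development, at -3.70 ± 0.23. Klrd1 (-3.72 ± 0.35), Gpr141b (-3.59 ± 0.42), Gpr33 (-3.45 ± 0.42), Cldn1 (-3.41 ± 0.26), Serpinb6b (-3.37 ± 0.27) and P2ry10 (-3.26 ± 0.57) completed the lowest genes, with Itgae. These genes were picked for passing the threshold without overlap between the arrays of the gates, so the lack of overlap is no added support. Limma's adjusted p ran from 1.1e-04 to 0.0136.

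The fixed macrophage lists were higher in CD11cint macrophages. Of the macrophage core list 20 of 22 tested members were higher and 0 lower (21 and 0 adjusted over the list alone), among them Selenop (3.09 ± 0.49), a selenium carrier, Mertk (2.96 ± 0.41), a receptor for dying cells, Mrc1 (2.78 ± 0.36), the mannose receptor, and Tlr7 (2.58 ± 0.39). Its list test gave adjusted p = 3.1e-22, and adjusted p = 0.184 with an estimated correlation. Of the colonic macrophage list 13 of 18 were higher (14 adjusted over the list alone). C1qa (3.32 ± 0.58) was among them, and the list had adjusted p = 1.8e-14, and adjusted p = 0.184 with an estimated correlation. Lysosomal genes were higher in 20 of 23 cases (23 adjusted over the list alone). They included the proteases Ctsl (2.27 ± 0.42), Ctsb (2.00 ± 0.24), Lgmn (1.97 ± 0.29) and Ctsd (1.89 ± 0.16), and the list had adjusted p = 7.0e-22, or adjusted p = 0.184 with an estimated correlation. Of phagocytosis and scavenger receptors 13 of 25 were higher (15 adjusted over the list alone). Msr1 (3.41 ± 0.60) was among them, and the list had adjusted p = 4.5e-11, and adjusted p = 0.184 with an estimated correlation. Complement genes were higher in 9 of 14 cases (9 adjusted over the list alone). C5ar1 stood at 3.33 ± 0.51 and C1qc at 3.24 ± 0.70, and the list had adjusted p = 4.4e-09, or adjusted p = 0.193 with an estimated correlation. The lists share members, Mrc1 for example, so their tests are not independent of each other.

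Chemokine genes were higher in 10 and lower in 2 of 21 cases (15 and 2 adjusted over the list alone). Cxcl13 (2.61 ± 0.48), a B cell attractant, was among the higher ones, and the list had adjusted p = 3.1e-09, or adjusted p = 0.184 with an estimated correlation. Among Toll-like receptors and adaptors 9 of 18 were higher and 1 lower (11 and 1 adjusted over the list alone). The higher ones included Ly96 (2.71 ± 0.27), the endotoxin co-receptor, Tlr8 (2.36 ± 0.28) and Tlr1 (2.24 ± 0.20), and the list had adjusted p = 2.9e-08, or adjusted p = 0.184 with an estimated correlation. Anti-inflammatory mediators were higher in 6 of 17 cases (12 adjusted over the list alone). Among them were Hmox1 (2.63 ± 0.40), the haem-degrading enzyme, and Stab1 (2.45 ± 0.35), with list adjusted p = 3.1e-08, and adjusted p = 0.184 with an estimated correlation. Inflammatory mediators were higher in 3 of 20 cases (9 adjusted over the list alone). These were Ccl3 (2.49 ± 0.64), Osm (1.72 ± 0.27) and Cxcl2 (1.37 ± 0.35), with list adjusted p = 1.6e-07, and adjusted p = 0.251 with an estimated correlation. Of iron and haem handling 8 of 16 were higher and 1 lower (9 and 1 adjusted over the list alone). The higher ones included the iron exporter Slc40a1 at 2.27 ± 0.26 and the ferroxidase Cp at 2.02 ± 0.26, and the list had adjusted p = 1.6e-07, or adjusted p = 0.184 with an estimated correlation. Of lipid handling 10 of 19 were higher and 2 lower (11 and 2 adjusted over the list alone). Apoe (3.03 ± 0.48), the cholesterol exporter Abca1 (2.65 ± 0.35) and Hpgds (2.29 ± 0.27) were higher and the leukotriene gene Alox5ap (-1.41 ± 0.24) lower, and the list had adjusted p = 1.5e-05, or adjusted p = 0.193 with an estimated correlation.

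Dendritic cell and proliferation lists were lower in CD11cint macrophages. Of the dendritic cell core list 0 of 21 were higher and 13 lower (0 and 16 adjusted over the list alone). The lower ones included Btla (-3.11 ± 0.25), an inhibitory receptor, and Ap1s3 (-2.87 ± 0.29), with list adjusted p = 4.2e-15, and adjusted p = 0.110 with an estimated correlation. Of the CD103 and type 1 dendritic list 10 of 18 were lower (1 higher and 14 lower adjusted over the list alone). Ly75 (-3.14 ± 0.28), an endocytic receptor, was among them, and the list had adjusted p = 1.1e-12, and adjusted p = 0.184 with an estimated correlation. Cell cycle genes were lower in 12 of 21 cases (17 adjusted over the list alone). They included the mitotic kinesins Kif11 (-2.50 ± 0.30) and Cenpe (-1.87 ± 0.18) and the survivin gene Birc5 (-1.73 ± 0.18), and the list had adjusted p = 5.0e-16, or adjusted p = 0.184 with an estimated correlation. Top2a, a topoisomerase of dividing cells, stood at -2.46 ± 0.27, while its other probe set gave -0.22, so this call rests on 1 probe set. Dendritic maturation and migration genes were lower in 6 of 17 cases (1 higher and 8 lower adjusted over the list alone). They included Cd200 (-1.67 ± 0.31), Ccl17 (-1.60 ± 0.33), Ccl22 (-1.42 ± 0.32) and Fscn1 (-1.39 ± 0.28), and the list had adjusted p = 0.0081, or adjusted p = 0.504 with an estimated correlation. The type 2 dendritic list had 3 higher and 2 lower of 11 (3 and 3 adjusted over the list alone). Those named by the rule were Clec4a1 (2.37 ± 0.37), Zeb2 (2.00 ± 0.28) and Sirpa (1.27 ± 0.20) higher and Cd209a (-1.80 ± 0.47) lower. Its median was -0.35, its mean 0.08 and its limma camera test pointed up with adjusted p = 0.882. MHC class II presentation had 1 higher and 2 lower of 11 (2 and 3 adjusted over the list alone), with H2-Ob (-1.81 ± 0.37) and H2-Oa (-1.59 ± 0.19), the chains of the peptide-loading inhibitor H2-O, lower and Ctss (0.87 ± 0.18) higher. Its median was 0.15, its mean -0.22 and its camera test pointed up with adjusted p = 0.883.

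**Figure D2:**
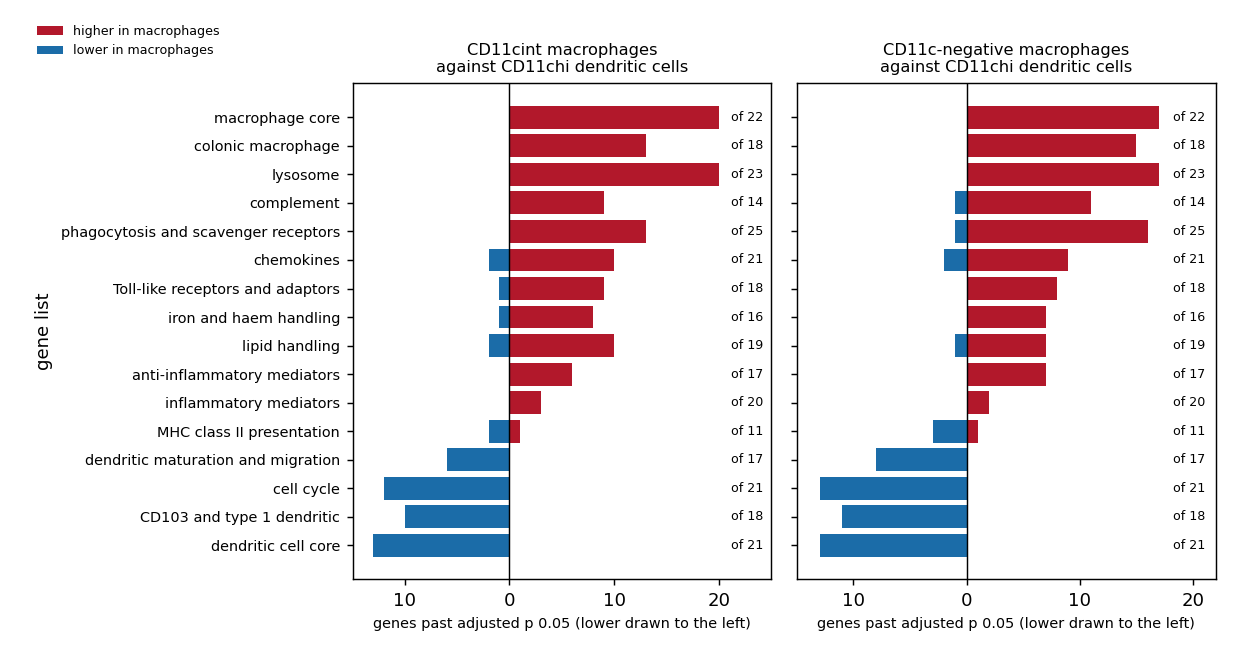
Number of genes past an adjusted p of 0.05 (horizontal axis, higher in macrophages to the right and lower to the left) in 16 of the 40 fixed gene lists (vertical axis), with the number of tested members at the right, for CD11cint macrophages (n = 3) and CD11c-negative macrophages (n = 2) against CD11chi dendritic cells (n = 3). In the left panel 20 of 22 macrophage core genes were higher and 13 of 21 dendritic cell core genes were lower.

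Between CD11cint macrophages and CD11chi dendritic cells, retinoic acid and TGF-beta genes had 4 higher and 0 lower of 12 (4 and 1 adjusted over the list alone), with Tgfbr1 (2.07 ± 0.29), Tgfbi (1.76 ± 0.30), Dhrs3 (1.37 ± 0.26) and Tgfbr2 (0.95 ± 0.20), and adjusted p = 0.120. The monocyte list had 1 higher, F13a1 (1.30 ± 0.30), and 2 lower of 12, Ifitm6 (-1.82 ± 0.43) and Plac8 (-1.54 ± 0.24), with the same counts adjusted over the list alone. Chemokine receptors had 5 higher and 3 lower of 12 (5 and 4 adjusted over the list alone), with Cx3cr1 (2.41 ± 0.37), the fractalkine receptor, Cmklr1 (2.27 ± 0.24) and Ccrl2 (1.82 ± 0.43) higher. The plasmacytoid dendritic list had Lair1 (2.81 ± 0.47) higher and Ccr9 (-1.46 ± 0.34) lower of 9 (2 and 1 adjusted over the list alone), and its median of -0.01 and mean of 0.28 differed in sign. Of the MHC class I list 2 of 10 were lower (3 adjusted over the list alone), Tap1 (-0.99 ± 0.23) and Psmb9 (-0.84 ± 0.18), with list adjusted p = 0.0567. Of the type I interferon response 2 of 16 were higher (5 higher and 1 lower adjusted over the list alone), Oas2 (0.83 ± 0.22) and Oasl2 (0.78 ± 0.20), with list adjusted p = 0.0087, and adjusted p = 0.414 with an estimated correlation. Immediate early and dissociation genes, which respond to tissue digestion, had Ier3 (1.22 ± 0.33) and Dusp1 (0.76 ± 0.13) higher of 17 (9 adjusted over the list alone), with list adjusted p = 3.1e-05, and adjusted p = 0.310 with an estimated correlation. Ribosomal protein genes had 0 of 13 past the threshold (0 adjusted over the list alone) at a median of -0.15, with list adjusted p = 0.0023, and adjusted p = 0.393 with an estimated correlation. Oxidative phosphorylation had 0 of 22 (0 adjusted over the list alone), with list adjusted p = 0.214.

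Markers of other cell types were measured on the same arrays. In the NK and innate lymphoid list 3 of 10 were lower in CD11cint macrophages (3 adjusted over the list alone), Klrd1, Klrk1 (-1.98 ± 0.30) and Tbx21 (-0.65 ± 0.17), with list adjusted p = 0.0023, and adjusted p = 0.348 with an estimated correlation. Gzma, a granzyme of cytotoxic lymphocytes, reached 11.43 on CD11chi dendritic replicate 1 and 10.92 on F4/80int replicate 1, against 5.71 to 9.03 on the other 8 arrays. Of the lineage antibody targets Cd3g and Cd3e were tested, and Cd3g differed by -2.09 ± 0.99 (adjusted p = 0.279) while Cd3e differed by -0.11 ± 0.12 (adjusted p = 0.718). The T cell list had 1 of 12 lower, Ctla4 (-1.20 ± 0.27), the B cell and plasma cell list 1 of 7 higher, Blnk, and the endothelium list 1 of 7 higher, Eng (0.59 ± 0.15), with the same counts adjusted over each list alone. The neutrophil list had 2 of 3 higher, Csf3r (1.39 ± 0.14) and Mmp9 (1.17 ± 0.22), and the mast cell and basophil list 1 of 3 lower, Kit (-2.74 ± 0.32), again with the same counts adjusted over each list alone. Kit is also on the dendritic cell core list, so its difference is no sign of mast cells in particular. Epithelial transcripts were high on every array, Krt8 at 9.04 to 10.69 and Car1 at 9.60 to 11.15, and 0 of 20 epithelium genes passed (0 adjusted over the list alone), with list adjusted p = 0.413. Of the stroma list 0 of 13 passed (2 higher adjusted over the list alone), with list adjusted p = 0.0141, and adjusted p = 0.424 with an estimated correlation. No tested member passed, also adjusted over each list alone, among 3 eosinophil genes (Siglecf, -0.08 ± 0.16), 2 erythrocyte genes (Car2, -0.15 ± 0.30), 1 gene of glia and neurons (Sox10, 0.07 ± 0.12) and 1 sex-linked gene (Xist, 0.09 ± 0.14). The sort marker list had 2 higher and 1 lower of 6 (the same adjusted over the list alone).

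In all, 969 genes differed between CD11cint macrophages and CD11chi dendritic cells at an adjusted p of 0.05, 578 higher and 391 lower in the macrophages, and 583 of them differed by more than 1 on the log2 scale. The count was 266 without the empirical Bayes prior, 619 without CD11cint macrophage replicate 1 and 598 without replicate 2. It was 580 without the 3 arrays that shared a pattern within their gates, which were CD11c-negative macrophage replicate 2, CD11chi dendritic replicate 3 and CD11cint macrophage replicate 3.

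CD11c-negative macrophages (n = 2) stood apart from CD11chi dendritic cells (n = 3) in chemokine genes, F13a1 and Cd163, among others. Pf4 was higher by 5.41 ± 0.47, Ccl8 by 4.76 ± 0.51, Ccl12 by 4.63 ± 0.64 and Cxcl13 by 4.46 ± 0.54. F13a1, the transglutaminase coagulation factor XIII A, was higher by 4.81 ± 0.34, with means of 11.20 and 6.39, and Cd163, the haemoglobin scavenger receptor, by 4.48 ± 0.31, with means of 10.57 and 6.10. Ms4a7 (4.23 ± 0.73), C3ar1 (4.14 ± 0.82) and Spic (3.78 ± 0.56) were again among the highest. P2ry10 (-4.68 ± 0.64), Gpr141b (-4.59 ± 0.46), Xcr1 (-4.34 ± 0.42), Flt3 (-4.29 ± 0.26), Serpinb6b (-4.22 ± 0.30), Klrd1 (-4.20 ± 0.39), Clec9a (-4.14 ± 0.58), Dpp4 (-4.02 ± 0.30) and Cldn1 (-3.93 ± 0.29) were the lowest, with Itgae. The arrays of the gates did not overlap for any of these genes, as the rule for picking them required, and limma's adjusted p ran from 4.1e-05 to 0.0106.

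Of the macrophage core list 17 of 22 were higher in CD11c-negative macrophages (21 adjusted over the list alone). They included Stab1 (3.60 ± 0.39), Mrc1 (3.53 ± 0.40), Selenop (3.42 ± 0.54) and Tlr7 (3.26 ± 0.44), and the list had adjusted p = 1.3e-21, or adjusted p = 0.184 with an estimated correlation. The colonic macrophage list had 15 of 18 higher (15 adjusted over the list alone), and iron and haem handling 7 of 16 (11 adjusted over the list alone), with Cp at 3.39 ± 0.29 and Hmox1 at 2.49 ± 0.45. Their list tests gave adjusted p = 1.4e-16 and 7.7e-11, and each had adjusted p = 0.184 with an estimated correlation. Phagocytosis and scavenger receptors had 16 higher and 1 lower of 25 (17 and 1 adjusted over the list alone), with list adjusted p = 8.8e-12, and adjusted p = 0.184 with an estimated correlation. The dendritic cell core list had 13 of 21 lower (15 adjusted over the list alone), with Ap1s3 at -3.64 ± 0.32, adjusted p = 1.9e-18, and adjusted p = 0.0837 with an estimated correlation. The CD103 and type 1 dendritic list had 11 of 18 lower (14 adjusted over the list alone), with Ly75 at -3.57 ± 0.32, adjusted p = 1.9e-16, and adjusted p = 0.184 with an estimated correlation. Dendritic maturation and migration genes were lower in 8 of 17 cases (9 adjusted over the list alone). The lowest were the T cell attractants Ccl17 (-3.43 ± 0.37) and Ccl22 (-3.18 ± 0.35) and the lymph node homing receptor Ccr7 (-2.02 ± 0.31), with list adjusted p = 4.4e-06, and adjusted p = 0.297 with an estimated correlation. Cell cycle genes were lower in 13 of 21 cases (18 adjusted over the list alone), with Kif11 at -2.39 ± 0.34 and Bub1 at -1.75 ± 0.27, adjusted p = 3.2e-16, and adjusted p = 0.184 with an estimated correlation.

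Inflammatory mediators were higher in 2 of 20 cases (3 higher and 1 lower adjusted over the list alone), Osm (1.34 ± 0.30) and Il18 (1.13 ± 0.24), with list adjusted p = 0.0434, and adjusted p = 0.615 with an estimated correlation. MHC class II presentation had 1 higher and 3 lower of 11 (1 and 4 adjusted over the list alone), with H2-Ob (-2.37 ± 0.42), H2-Oa (-2.22 ± 0.22) and H2-Eb2 (-1.69 ± 0.34) lower, a median of 0.10, a mean of -0.44 and adjusted p = 0.490. The monocyte list had 1 of 12 higher (1 adjusted over the list alone), F13a1, with list adjusted p = 0.0563. Stroma genes were higher in 5 of 13 cases (5 adjusted over the list alone). Dcn (1.82 ± 0.47), Mgp (1.54 ± 0.24) and Acta2 (1.23 ± 0.24) were among them, and the list had adjusted p = 2.8e-04, or adjusted p = 0.295 with an estimated correlation. The epithelium list had 0 of 20 past the threshold (0 adjusted over the list alone) at a median of 0.64, with list adjusted p = 0.0031, and adjusted p = 0.582 with an estimated correlation. In the NK and innate lymphoid list 3 of 10 were lower (4 adjusted over the list alone), at a median of -0.73, with list adjusted p = 0.0016, and adjusted p = 0.342 with an estimated correlation. Immediate early and dissociation genes had 2 of 17 higher (2 adjusted over the list alone), at a median of 0.40, with list adjusted p = 0.0023, and adjusted p = 0.423 with an estimated correlation. In all, 1022 genes differed, 609 higher and 413 lower in CD11c-negative macrophages, and 657 by more than 1. The count was 371 without the empirical Bayes prior, 527 without the 3 arrays of the shared pattern, 367 without CD11c-negative macrophage replicate 1 and 594 without replicate 2, where the lone array left was assumed to vary like those of the other gates.

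The comparisons of the macrophage gates with CD11chi dendritic cells shared their calls to a large extent. In both comparisons 407 genes were higher and 301 lower, 708 in all, and 0 were called in opposite directions, where independent lists would share 29.3 and 13.4. Across genes, which are not independent replicates, the differences correlated at 0.89 with a covariance of 0.265. In 100 simulated sets of unchanged gates against shared dendritic arrays the correlation was 0.45 and the covariance 0.026. The overlap there was at most 0 genes, since no gate differed, and did not measure what sharing adds to the 708. The 3 dendritic arrays were not split between the comparisons, so part of the excess in the number of shared calls may come from the shared arrays. The direct test of the macrophage gates against each other is the measure of where they differ.

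CD11c-negative macrophages (n = 2) and CD11cint macrophages (n = 3) differed in a small set of genes, with F13a1 and Cd163 at the largest increases. F13a1 was higher in CD11c-negative macrophages by 3.52 ± 0.34 (SE), with means of 11.20 and 7.69, and Cd163 by 3.39 ± 0.31, with means of 10.57 and 7.18. Cbr2, a carbonyl reductase, was higher by 3.01 ± 0.36, Lyve1, a hyaluronan receptor also found on lymphatic vessels, by 2.81 ± 0.22, and Cd209f, a C-type lectin, by 2.42 ± 0.34. Folr2, a folate receptor, was higher by 1.38 ± 0.17, and C4b, a complement component, by 1.66 ± 0.23. Mmp12, the macrophage elastase, was lower by 2.21 on this scale (SE 0.34), and Sh2d1b1 (-1.91 ± 0.28), the tryptophan-degrading enzyme Kynu (-1.77 ± 0.18) and Stra6l (-1.34 ± 0.19) were lower too. Itgax stood at -2.03 ± 0.19, as the gates require. The arrays of the gates did not overlap for these genes, as for all 16 genes past the threshold. The rule for the highest and lowest genes required it.

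**Figure D3:**
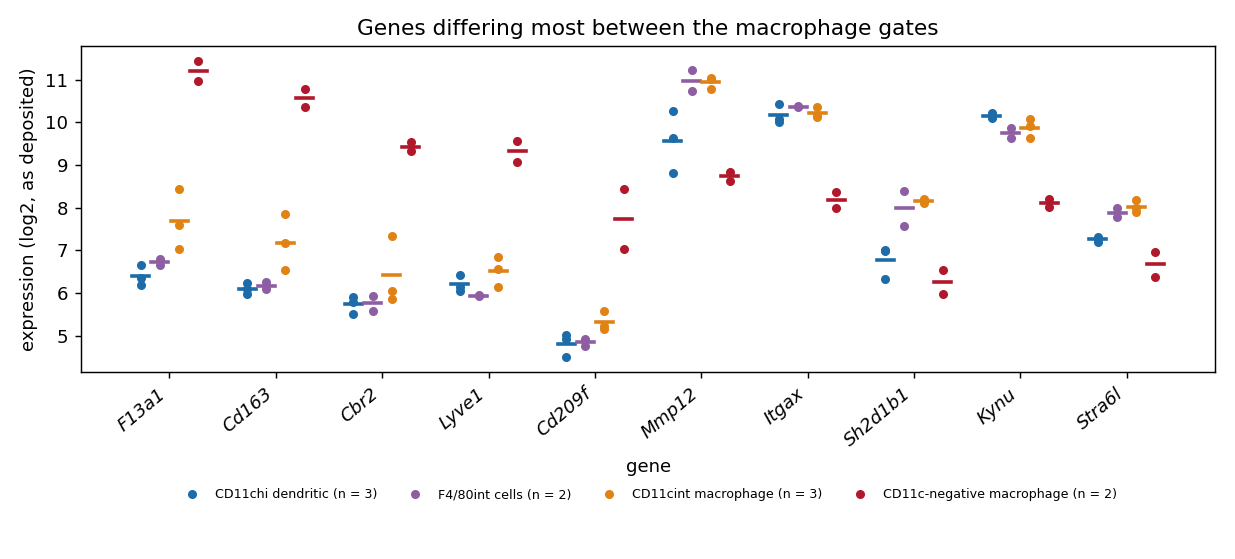
Expression on the log2 scale as deposited (vertical axis) of the 5 highest and 5 lowest genes of the comparison of CD11c-negative macrophages (n = 2) with CD11cint macrophages (n = 3), for all 4 gates (horizontal axis gives the gene), with 1 point per array and 1 bar per mean. F13a1 and Cd163 reached 11.20 and 10.57 on average in CD11c-negative macrophages, above every array of the other gates.

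Of the colonic macrophage list 3 of 18 were higher in CD11c-negative macrophages, Cd163, Lyve1 and Folr2 (4 higher and 1 lower adjusted over the list alone), with list adjusted p = 1.5e-05, and adjusted p = 0.331 with an estimated correlation. The monocyte list had 1 of 12 higher, F13a1 (1 adjusted over the list alone), with list adjusted p = 0.0024, and adjusted p = 0.198 with an estimated correlation. Phagocytosis and scavenger receptors had 2 of 25 higher (5 higher and 1 lower adjusted over the list alone), with list adjusted p = 0.0057, and adjusted p = 0.424 with an estimated correlation. Complement had C4b higher and Itgax lower of 14 (3 and 1 adjusted over the list alone), with list adjusted p = 0.0171, and adjusted p = 0.512 with an estimated correlation. Inflammatory mediators had 0 of 20 past the threshold (1 lower adjusted over the list alone), a median of -0.44, and the list had adjusted p = 2.9e-06, or adjusted p = 0.297 with an estimated correlation, with the most highly expressed members at -0.22 ± 0.17 for Il1b and -0.52 ± 0.25 for Ptgs2 (adjusted p = 1.00 for both). Dendritic maturation and migration genes had 0 of 17 (4 lower adjusted over the list alone), with Apol7c at -2.06 ± 0.36 (adjusted p = 0.0792), list adjusted p = 2.5e-06, and adjusted p = 0.295 with an estimated correlation. Of the dendritic cell core list 0 of 21 passed (3 lower adjusted over the list alone), with list adjusted p = 7.5e-06, and adjusted p = 0.184 with an estimated correlation. Of the macrophage core list 0 of 22 passed (0 adjusted over the list alone), with list adjusted p = 0.0126, and adjusted p = 0.597 with an estimated correlation. Chemokines had 0 of 21 (5 higher and 2 lower adjusted over the list alone), a median of -0.09, a mean of 0.13 and adjusted p = 0.708. The epithelium list had 0 of 20 (0 adjusted over the list alone), a median of 0.42, and the list had adjusted p = 1.2e-04, or adjusted p = 0.468 with an estimated correlation, and the stroma list 0 of 13 (2 higher adjusted over the list alone), with list adjusted p = 0.0023, and adjusted p = 0.342 with an estimated correlation.

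By limma 16 genes differed between the macrophage gates at an adjusted p of 0.05, 10 higher and 6 lower in CD11c-negative macrophages, and 518 had an unadjusted p under 0.05. The balance of directions was not stable, since 42.3% of calls were higher with only these gates in the model, against 62.5% with all gates. The count was 26 with only these gates in the model, 0 without the empirical Bayes prior, 1 without CD11c-negative macrophage replicate 1, and 10 without CD11cint macrophage replicate 1 or replicate 2. The lone array left without CD11c-negative macrophage replicate 1 was assumed to vary like those of the other gates.

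F4/80int cells (n = 2) differed from CD11chi dendritic cells (n = 3) in 2 genes at an adjusted p of 0.05. Adgre4, an adhesion receptor of the same family as F4/80, was higher in F4/80int cells by 2.01 ± 0.19 (SE; adjusted p = 0.0058), with means of 7.76 and 5.76. Mns1 was lower, at -1.52 ± 0.18 (adjusted p = 0.0257), with means of 6.45 and 7.97. For both genes the arrays did not overlap, as the naming rule required. The F4/80int arrays lay near the macrophage gates, which had means of 7.69 and 7.38 for Adgre4 and 6.08 and 5.99 for Mns1. Genes of dendritic cells had small differences, with Itgae at -0.29 ± 0.32 (adjusted p = 0.914) and Ccr7 at 0.19 ± 0.31 (adjusted p = 0.938).

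Macrophage lists had medians above CD11chi dendritic cells, without any member past the threshold over all genes. The F4/80int arrays differed, with replicate 2 the higher in the lists given by array. As the median deviation of a list's genes from their means over all arrays, complement stood at -0.79 on F4/80int replicate 1 and 0.45 on replicate 2, against -1.59, -0.85 and -0.71 on the CD11chi dendritic arrays. Inflammatory mediators stood at -0.16 and 0.94, against -1.03, 0.01 and -0.68. For both of these lists replicate 1 lay within the range of the CD11chi dendritic arrays, and only replicate 2 lay above it. The macrophage core list stood at -0.61 and 0.27, against -1.45, -1.09 and -0.89. The macrophage core list had a median of 0.87 and 0 of 22 past the threshold (8 higher adjusted over the list alone), with Lyz2 at 0.91 ± 0.23 by limma (adjusted p = 0.314), list adjusted p = 7.2e-15, and adjusted p = 0.184 with an estimated correlation. Lysosomal genes had a median of 0.54 and 0 of 23 (11 higher adjusted over the list alone), with list adjusted p = 5.0e-16, and adjusted p = 0.184 with an estimated correlation. Complement genes had a median of 1.01 and 0 of 14 (6 higher adjusted over the list alone), with C3ar1 at 2.34 ± 0.82 (adjusted p = 0.603), list adjusted p = 3.1e-06, and adjusted p = 0.260 with an estimated correlation. Inflammatory mediators had a median of 1.00 and 0 of 20 (0 adjusted over the list alone), with Ptgs2 at 0.78 ± 0.25 (adjusted p = 0.485), list adjusted p = 8.0e-09, and adjusted p = 0.215 with an estimated correlation. Immediate early and dissociation genes also had a median above 0, 0.35, and 0 of 17 (1 higher adjusted over the list alone), with list adjusted p = 1.5e-05, and adjusted p = 0.297 with an estimated correlation. The monocyte list had a median of 0.29 and 0 of 12 (2 higher adjusted over the list alone), with list adjusted p = 6.7e-04, and adjusted p = 0.184 with an estimated correlation. Type 2 dendritic genes had a median of 0.19 and 0 of 11 (3 higher adjusted over the list alone), with Sirpa at 1.00 ± 0.22 (adjusted p = 0.227), list adjusted p = 0.0029, and adjusted p = 0.193 with an estimated correlation. Dendritic cell core genes had 0 of 21 (0 adjusted over the list alone) and adjusted p = 0.153, CD103 and type 1 dendritic genes 0 of 18 (0 adjusted over the list alone) and a median of -0.11. Cell cycle genes had 0 of 21 (1 lower adjusted over the list alone), a median of -0.18, adjusted p = 4.7e-04, and adjusted p = 0.396 with an estimated correlation. Gzma differed by -0.67 ± 1.06 (adjusted p = 0.938), with high values on 1 array of each gate.

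By limma, 1 of the 2 genes was higher and 1 lower, and 839 genes had an unadjusted p under 0.05. In data simulated with the same gate sizes 62% of genes changed by 1 and 96% of genes changed by 2 on the log2 scale were recovered. Those data had 50 changed genes of each size, and each gene had the same spread in every gate. They do not show how many real differences were missed here. With arrays scaled to the same 75th percentile 3 genes were called, 66.7% of them higher, against 1 of 2 as deposited. The count was 50 without F4/80int replicate 1, 0 without F4/80int replicate 2, 11 without CD11chi dendritic replicate 2, and 1 without either CD11c-negative macrophage array or without CD11cint macrophage replicate 1 or 2. It was 55 without CD11chi dendritic replicate 1 and F4/80int replicate 1, 0 without the 3 arrays of the shared pattern, 0 without the empirical Bayes prior, 0 with only these gates in the model and 1 without the intensity trend, and a lone F4/80int array was assumed to vary like those of the other gates.

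Against CD11cint macrophages (n = 3), F4/80int cells (n = 2) had higher levels of dendritic cell genes, type 1 genes among them. Xcr1 was higher by 4.07 ± 0.42 (SE), with means of 9.59 and 5.52, Flt3 by 3.18 ± 0.26 and Clec9a by 2.97 ± 0.58. Klrd1, of the NK and innate lymphoid list, was higher by 2.71 ± 0.39. Gpr141b (3.57 ± 0.46), Cldn1 (3.22 ± 0.29), Ap1s3 (3.10 ± 0.32), Gpr33 (2.99 ± 0.46) and Rasgrp3 (2.92 ± 0.50) were higher too, with Itgae at 3.48 ± 0.32. The lowest genes in F4/80int cells were Ccl8 (-3.26 ± 0.51), Spic (-3.02 ± 0.56), Pf4 (-2.57 ± 0.47), Bhlhe41 (-2.23 ± 0.38), Bank1 (-2.16 ± 0.37), the growth factors Igf1 and Pdgfc (-1.94 ± 0.37), Gdpd1 (-1.85 ± 0.34), Cp (-1.82 ± 0.29) and Rcbtb2 (-1.71 ± 0.33). The arrays of the gates did not overlap for these genes, which were picked by that rule, and limma's adjusted p ran from 9.0e-04 to 0.0474.

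Of the dendritic cell core list 8 of 21 were higher in F4/80int cells (15 adjusted over the list alone). These included Btla (2.58 ± 0.28) and Kmo (2.11 ± 0.40), an enzyme of tryptophan breakdown, with list adjusted p = 4.7e-19, and adjusted p = 0.0837 with an estimated correlation. The CD103 and type 1 dendritic list had 8 of 18 higher (13 adjusted over the list alone), with Ly75 at 2.35 ± 0.32, adjusted p = 1.9e-16, and adjusted p = 0.184 with an estimated correlation. Cell cycle genes were higher in 4 of 21 cases (12 adjusted over the list alone), Kif11 (2.33 ± 0.34), Bub1 (1.50 ± 0.27), Cenpe (1.38 ± 0.20) and Top2a (1.87 ± 0.30, with the opposite sign, -0.07, for its other probe set), with list adjusted p = 4.1e-14, and adjusted p = 0.184 with an estimated correlation. The colonic macrophage list had 2 of 18 lower, Ccl8 and Hpgd (-1.57 ± 0.30), a prostaglandin-degrading enzyme (9 adjusted over the list alone), with list adjusted p = 4.8e-10, and adjusted p = 0.199 with an estimated correlation. Of the macrophage core list 0 of 22 passed (12 lower adjusted over the list alone), with Lyz2 at -0.50 ± 0.23 (adjusted p = 0.421), list adjusted p = 3.4e-13, and adjusted p = 0.195 with an estimated correlation. Lysosomal genes had Ctsd (-0.98 ± 0.18) lower of 23 (9 adjusted over the list alone), with list adjusted p = 6.4e-11, and adjusted p = 0.203 with an estimated correlation. H2-Oa (1.45 ± 0.22) was higher among 11 MHC class II presentation genes (3 adjusted over the list alone), Alox5ap (1.44 ± 0.27) among 19 lipid handling genes (3 higher and 6 lower adjusted over the list alone), and Kit (2.03 ± 0.36), also on the dendritic cell core list, among 3 mast cell and basophil genes (1 adjusted over the list alone). Inflammatory mediators had 0 of 20 (0 adjusted over the list alone), with Il1b at 0.08 ± 0.17 (adjusted p = 0.910) and list adjusted p = 0.289. The NK and innate lymphoid list had Klrd1 and Klrk1 (1.82 ± 0.33) higher of 10 (2 adjusted over the list alone), with list adjusted p = 0.0055, and adjusted p = 0.392 with an estimated correlation. Of the stroma list 0 of 13 passed (1 lower adjusted over the list alone) at a median of -0.35, with list adjusted p = 4.0e-05, and adjusted p = 0.245 with an estimated correlation.

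In all, 93 genes differed, 73 higher and 20 lower in F4/80int cells, and 81 by more than 1. The count was 11 without F4/80int replicate 1, 351 without F4/80int replicate 2, 25, 34 and 53 without CD11cint macrophage replicates 1, 2 and 3, and 0 without the empirical Bayes prior. It was 43 without the 3 arrays of the shared pattern and 14 without CD11chi dendritic replicate 1 and F4/80int replicate 1, and a lone F4/80int array was assumed to vary like those of the other gates.

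Against CD11c-negative macrophages (n = 2), F4/80int cells (n = 2) again had higher levels of dendritic cell genes. Gpr141b was higher by 4.57 ± 0.51 (SE), Xcr1 by 4.14 ± 0.46, P2ry10 by 4.10 ± 0.70 and Ap1s3 by 3.87 ± 0.35, with Itgae at 3.84 ± 0.35. F13a1 (-4.48 ± 0.37), Ccl8 (-4.42 ± 0.56), Cd163 (-4.40 ± 0.34), Cbr2 (-3.67 ± 0.39) and Cxcl13 (-3.47 ± 0.59) were the lowest. Again the rule picked genes past the threshold without overlap between arrays, and limma's adjusted p ran from 2.0e-04 to 0.0146. The dendritic cell core list had 11 of 21 higher (13 adjusted over the list alone), with Flt3 (3.78 ± 0.28) and Dpp4 (3.65 ± 0.33), adjusted p = 1.3e-21, and adjusted p = 0.0837 with an estimated correlation. The colonic macrophage list had 7 of 18 lower (1 higher and 9 lower adjusted over the list alone), with Lyve1 (-3.38 ± 0.24) and Vsig4 (-2.31 ± 0.39), a complement receptor, adjusted p = 2.2e-12, and adjusted p = 0.184 with an estimated correlation. Dendritic maturation and migration genes were higher in 4 of 17 cases (7 adjusted over the list alone), Ccl17 (3.37 ± 0.41), Ccl22 (3.12 ± 0.39), Ccr7 (2.21 ± 0.34) and Apol7c (2.15 ± 0.39), with list adjusted p = 3.1e-08, and adjusted p = 0.223 with an estimated correlation. MHC class II presentation had 4 of 11 higher (4 adjusted over the list alone), with H2-Ob (2.15 ± 0.46), H2-Eb2 (2.13 ± 0.37), H2-Oa (2.08 ± 0.24) and Ifi30 (0.72 ± 0.16), adjusted p = 0.0048, and adjusted p = 0.415 with an estimated correlation. Aldh1a2, a retinoic acid synthesis enzyme of migratory dendritic cells, was higher by 1.76 ± 0.40 (adjusted p = 0.0498), as 1 of 12 retinoic acid and TGF-beta genes (1 higher and 3 lower adjusted over the list alone). Cell cycle genes were higher in 7 of 21 cases (13 adjusted over the list alone), with Kif11 at 2.23 ± 0.37, adjusted p = 6.4e-14, and adjusted p = 0.184 with an estimated correlation. Stroma genes were lower in 3 of 13 cases (6 adjusted over the list alone), Mgp (-1.57 ± 0.26), Bgn (-1.06 ± 0.19) and Acta2, with list adjusted p = 2.7e-07, and adjusted p = 0.184 with an estimated correlation, and the epithelium list had 0 of 20 (0 adjusted over the list alone) at a median of -0.56, with list adjusted p = 0.0022, and adjusted p = 0.564 with an estimated correlation. NK and innate lymphoid genes were higher in 2 of 10 cases (2 adjusted over the list alone), Klrd1 and Klrk1 (1.96 ± 0.36), with list adjusted p = 0.0039, and adjusted p = 0.376 with an estimated correlation. In all, 280 genes differed, 163 higher and 117 lower in F4/80int cells, and 233 by more than 1. The count was 63 without CD11c-negative macrophage replicate 1, 140 without replicate 2, 55 without F4/80int replicate 1, 37 without the empirical Bayes prior, 165 without the 3 arrays of the shared pattern and 63 without CD11chi dendritic replicate 1 and F4/80int replicate 1, with any lone array of a gate assumed to vary like those of the other gates.

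Each array was also placed between CD11chi dendritic cells and CD11cint macrophages, over the 583 genes that differed between them by more than 1, as a position of 0 at the dendritic mean and 1 at the macrophage mean. F4/80int replicate 1 had a median position of 0.17 (interquartile range over genes, -0.00 to 0.40) and F4/80int replicate 2 one of 0.62 (0.37 to 0.79), with a mean of 0.40 ± 0.32 (SD, n = 2). Over the 377 genes higher in macrophages the medians were 0.29 and 0.74, and over the 206 genes higher in dendritic cells 0.02 and 0.34. Flt3, an example chosen after the values were seen, stood at 10.04 and 9.25 on the F4/80int arrays, against means of 10.16 in CD11chi dendritic cells and 6.46 in CD11cint macrophages, while Ms4a7, chosen in the same way, stood at 8.38 and 11.05 against means of 7.22 and 11.49. The CD11c-negative macrophage arrays had positions of 1.04 and 0.97 and the CD11cint macrophage arrays lay at 0.98 to 1.03. No gene was past the threshold in the same direction against both CD11chi dendritic cells and CD11cint macrophages, with 0 higher than both and 0 lower than both, and 839 and 1444 genes had an unadjusted p under 0.05 in these comparisons. Only 2 genes passed against CD11chi dendritic cells, so this overlap had little room to differ from 0. It does not show whether F4/80int cells have genes of their own. With the genes chosen anew, the position was 0.63 without F4/80int replicate 1 and 0.16 without F4/80int replicate 2.

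**Figure D4:**
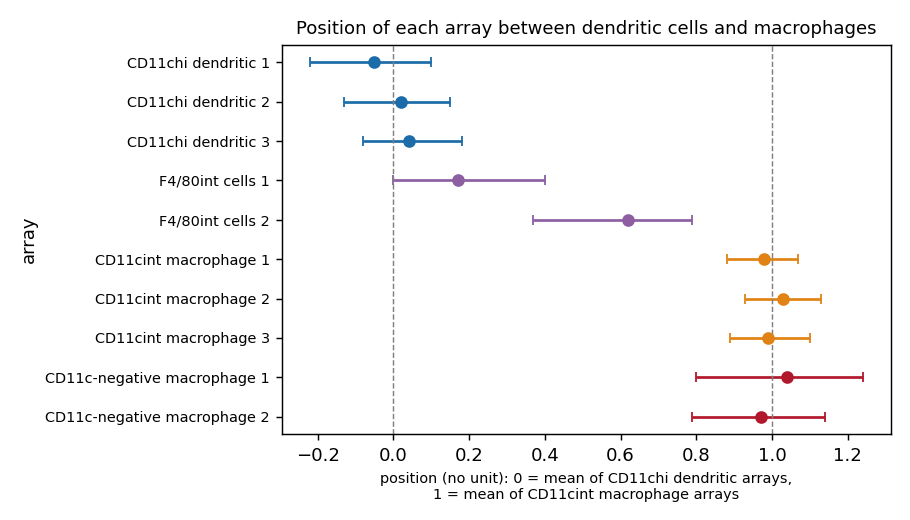
Median position of each array (vertical axis) over 583 genes between the mean of the CD11chi dendritic arrays, 0, and the mean of the CD11cint macrophage arrays, 1 (horizontal axis, no unit), with lines for the interquartile range over genes. The F4/80int arrays lie at 0.17 and 0.62, and the CD11c-negative macrophage arrays at 1.04 and 0.97.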

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

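The fits without 3 arrays that share a pattern within their gates and without 2 arrays with lymphocyte transcripts were chosen after the values were seen. Offsets before the logarithm were not run, because the deposited values are already on the log2 scale. Quantile normalization, 75th percentile scaling, no filter, a filter on the mean, the mean of a gene's probe sets and tests of every probe set left the 6 counts of genes within 1.5 times their values. Of 543 values for named genes 288 were called. Of these calls 236 kept their direction and their side of the threshold under each of these alternatives, without an intensity trend, with only the gates compared and with the replicate block, and 0 reversed. With only the gates compared 38 calls were lost, without a filter 23, with quantile normalization 11, and without the empirical Bayes prior 196.

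The counts below are of F4/80int cells against CD11chi dendritic cells unless another comparison is named. Without an intensity trend the count was 1. With only the gates compared it was 0, and 26 for CD11c-negative against CD11cint macrophages. With the replicate block it was 4, and 33 for the macrophage gates. The block gave 1229 and 1187 for CD11cint and CD11c-negative macrophages against dendritic cells, and 136 and 395 for F4/80int cells against CD11cint and CD11c-negative macrophages. The labels do not say that numbers pair samples. Over 13 pairs of arrays with the same number the correlation of deviations ran from -0.42 to 0.46 and was over 0.1 in 8, and 6 of 10 arrays correlated best with an array of their own number. The 3 pairs of CD11chi dendritic cells with CD11cint macrophages had 0.19, 0.15 and 0.46. Without the empirical Bayes prior the 6 counts were 266 and 371 for CD11cint and CD11c-negative macrophages against dendritic cells, 0 here, 0 for F4/80int cells against CD11cint macrophages, 0 between the macrophage gates and 37 for F4/80int cells against CD11c-negative macrophages, where the test has 6 residual degrees of freedom and no pooling of spread over genes. Without the 3 arrays that share a pattern the counts in that order were 580, 527, 0, 43, 11 and 165. Without the 2 arrays with lymphocyte transcripts they were 827, 881, 55, 14, 20 and 63. These fits have fewer arrays. Leaving out CD11chi dendritic replicate 1 alone gave 3, 109 and 287 in the comparisons of F4/80int cells, in the same order. The larger moves without both arrays thus came with leaving out F4/80int replicate 1, which leaves replicate 2 as the lone array of its gate. That fit does not separate lymphocyte transcripts from the loss of this array. Apart from that the cause was not tested.

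Leaving out each array in turn gave 598 to 1002 genes for CD11cint macrophages and 367 to 1032 for CD11c-negative macrophages against CD11chi dendritic cells. It gave 0 to 50 for F4/80int against CD11chi dendritic cells, 11 to 351 for F4/80int cells against CD11cint macrophages, 1 to 22 between the macrophage gates and 55 to 382 for F4/80int cells against CD11c-negative macrophages. A lone array left in a gate was assumed to vary like the other gates. The position of the F4/80int arrays ran from 0.16 to 0.63, and was 0.40 with all arrays and 0.27 with CD11c-negative macrophages as the reference. The list tests past the threshold numbered 106 to 118, against 113 with all arrays, 111 with quantile normalization, 121 with the replicate block and 0 with an estimated correlation.

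List directions turned in 2 tests that had not passed with all arrays. Epithelium, F4/80int against CD11chi dendritic cells, had adjusted p = 0.0013 without CD11chi dendritic replicate 2, against 0.925 with all arrays and a range of 0.0013 to 0.975 over 13 alternatives, with 0.953 as the highest among those leaving out 1 array. The type I interferon response, F4/80int cells against CD11cint macrophages, had adjusted p = 0.0371 without F4/80int replicate 1, against 0.861 with all arrays and a range of 0.0371 to 0.965, with 0.882 as the highest on leaving out 1 array. The cause was not tested. Background estimates were not used here, so how far low signal limits small differences is unknown.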

Other observations

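The tests of a mixture, a swapped label, lymphoid cells, a common technical shift and a handling batch were chosen after the result was seen, and those of epithelial carry-over, a dissociation response and other splits before.

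F4/80int replicate 2 had a median position of 0.62, between CD11chi dendritic arrays (-0.05 to 0.04) and CD11cint macrophage arrays (0.98 to 1.03), while F4/80int replicate 1 lay at 0.17. A label swapped with another gate would put the array near that gate's range, and 0.62 lies outside each. The CD11chi dendritic and CD11cint macrophage ranges come from the arrays that set 0 and 1, so they may be too narrow. The CD11c-negative macrophage arrays, which did not set this scale, lay at 0.97 to 1.04. A mixture of macrophages and dendritic cells may account for it. On the linear scale the macrophage share was 0.50 from 114 genes high in macrophages (interquartile range 0.38 to 0.62) and 0.50 from 43 genes high in dendritic cells (0.40 to 0.64), a difference of 0.007, with F4/80int replicate 1 as the dendritic endpoint. With the mean of the CD11chi dendritic arrays as that endpoint the shares were 0.57 and 0.53, further apart. Cells that each hold an intermediate state were not tested and stay open, because a pooled sample does not separate them from a mixture.

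The NK and innate lymphoid list lay above the other arrays of the gate by a median of 0.89 on CD11chi dendritic replicate 1 and 0.93 on F4/80int replicate 1, where the 95th percentile of random lists was 0.16 and 0.14, but F4/80int replicate 2 is the only other array of its gate, so part of the 0.93 may come from low values there (-0.11 against the means over all arrays, with 0.77 on replicate 1 and 0.01 and 0.04 on CD11chi dendritic replicates 2 and 3). These arrays were singled out after their lymphocyte transcripts were seen, and the list holds some of these transcripts. Random lists were not chosen for shared expression, so passing their percentile adds no independent support. NK or other lymphoid cells among the sorted cells are a candidate source, with Gzma at 11.43 and 10.92, Gzmb at 8.63 and 8.64, Nkg7 at 8.16 and 7.52 and Cd3g at 10.74 and 9.06. Of 10 members 5 and 4 exceeded 1, Prf1 stayed at 6.26 and 6.32, and the epithelium list was also in excess on these arrays, by 0.23 and 0.55, so that the lymphoid list did not move alone. The T cell list, which holds Cd3g, was in excess by a median of 0.30 and 0.09, with 3 and 1 of 12 members over 1. The gates took cells with high MHC class II and removed CD19, CD3 and TCR-bearing cells, and dendritic cells may carry some of these transcripts themselves, since Klrd1 was high on all CD11chi dendritic arrays. A technical shift common to both arrays stays open, with a correlation of 0.15 between their deviations outside the T cell and NK lists.

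CD11c-negative macrophage replicate 2, CD11chi dendritic replicate 3 and CD11cint macrophage replicate 3 shared deviations from their gate means, for example in Tnip3 (1.93, 1.71 and 2.45), Slc7a11 (1.77, 1.74 and 1.70) and Muc2 (1.49, 1.57 and 1.61). A rise of the fixed immediate early and dissociation genes common to the 3 arrays is argued against. Their list had median excesses of 0.25, 0.06 and -0.17 and upper quartiles of 0.51, 0.24 and 0.03. Only the CD11c-negative macrophage array lay above the 95th percentile of random lists (0.12 there). A dissociation response in genes outside this list was not tested and stays open. A shared handling batch may account for the pattern, with a mean correlation of 0.38 against at most 0.25 for the other 17 choices of 1 array per gate, but the arrays were picked for it and the labels give no dates. Epithelial carry-over stays open. The epithelium list was in excess by 0.14, 0.76 and 0.52, which met the planned criterion, but a comparison added after the result was seen found 2 other arrays at or above the lowest of these, CD11chi dendritic replicate 1 (0.23) and F4/80int replicate 1 (0.55), and no biological explanation was tested.

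For CD11cint macrophages against CD11chi dendritic cells, 1 of the 10 splits of the 6 arrays into groups of 3, the real one, gave as many genes. With only these arrays in the model it called 947 genes, and the highest other split called 0. Each other split put arrays of both gates into each group, so the difference between gates widened the spread within its groups. The distance from 947 to 0 is therefore no measure of strength. With 10 splits no share under 0.05 can be reached.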
